A study of Homo sapiens with 4 samples.

How the data were processed

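H3K14ac, acetylation of lysine 14 on histone H3, was profiled by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in MKN45, an established gastric cancer cell line. The 4 samples were 1 H3K14ac library and 1 input library (sonicated chromatin without antibody) from cells with a control short hairpin RNA (shNT), and the same pair from cells with a hairpin against NIT2 (shNIT2). The samples were grouped by the hairpin and the antibody named in the labels. The values used came from 2 peak lists, one per H3K14ac library. The reads of those libraries and any values of the 2 input libraries were not used here.

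Single-end reads came from formaldehyde-fixed, sonicated chromatin, per the labels' protocols. The submitters' processing notes name cutadapt 1.9.1, Trimmomatic 0.35, FastQC, Bowtie2 2.2.6, MACS2 2.1.1, ChIPseeker and the genome build hg38. Whether the input libraries served as the peak caller's control, and how duplicate and multiply mapped reads were treated, is not given in the sources used here. Each deposited list was called on 1 library, so replicates cannot be compared. Per peak, the deposited lists hold a score, a fold enrichment (the ratio of the fragment pileup at the summit to the background, with a pseudocount of 1 added to each), the −log10 p-value, the −log10 q-value and the summit's place in the peak. These per-peak values are the authors' own. As they stand, they were used to describe, rank or filter peaks within a list. The pileups and backgrounds solved from them (below) were also compared between the lists, to weigh depth. The smallest −log10 q in the deposited lists was 1.30 in both, which is a q threshold of 0.05.

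Genes came from a RefSeq table of the assembly GRCh38.p14, whose chromosomes are those of hg38. Its 20037 protein-coding genes carry a start and an end, but neither strand nor exons. Promoters were therefore replaced by windows of 1 kb on each side of both ends of a gene, called gene ends below, and a gene was marked when a peak region touched such a window by at least 1 bp. Transcription start and termination sites could not be separated, and exons and introns were not distinguished. A region that marks a gene may lie outside it and could belong to a neighbour. Among others, this was so in the knockdown list for SENP3, DENND3, MRPL2, CD68, COX19, TYMP and RRM2. In the control list it was so for MYMX, SLC29A1, FBXL4, OOSP2, DYNLT2B, MADCAM1, SMG6 and HEMK2. A region took the class of its midpoint: gene end, inside a gene, or between genes. No rows within a list overlapped, so each peak is one region. Coordinates are 1-based on hg38.

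Regions were shared when they overlapped by at least 1 bp, and 1000 seeded circular shifts of one list along its chromosomes gave the overlap by random placement. The shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. With 1 library per condition there was no test across samples. Of 27 gene lists fixed before the data were examined, all 716 genes were found in the gene table. For each list, the members marked in shNIT2 alone minus those in shNT alone were placed among 10000 random lists of the same size, matched in 10 bins on the mean within-list rank of the strongest region at the gene end. This rank is itself drawn from the peaks, and genes marked in neither list form a bin of their own. A matched list therefore holds as many marked genes as the real one by construction. A gene marked in one list alone takes the lowest rank in the other, so the mean rank also partly fixes how marked genes divide between the lists. The matched percentile can therefore show little about that division. The unmatched percentile compares the same difference with genes at large. Genes marked in both lists add nothing to the difference, so it does not measure how many genes are marked.

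The fragment pileup and the background behind each peak were solved from the authors' fold and −log10 p, using the Poisson upper tail. A whole-number pileup was recovered for 99.96% of regions in each list within 0.1% of the −log10 p. It was not recovered for 15 shNT and 11 shNIT2 regions. The lowest background is the genome-wide floor, which rises with depth and fragment length. The floor was 0.278 fragments in shNT and 2.48 in shNIT2, a ratio of 8.93, or 7.86 after division by the shortest region of each list. Total reads per library are unknown. In simulated peaks the same solution recovered 98.6% of 1675 pileups. The random-list percentile lay beyond its limits of 2.5 and 97.5 in 4% of 200 simulated lists without a change and in 100% of 50 lists with one. The simulated change was a large rise in the share of counted members among genes that have a rank. Smaller changes and the sizes of the real lists were not simulated. Before the change, that share was the same at every rank, whereas in the data the rank partly fixes the outcome. The 100% therefore does not show how well a change in the real lists would be found.

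The genes named were fixed by rule before the data were examined, except where the text says that a gene was named after its values were seen. They are NIT2, RELA, BRD1 and KAT7, and the 5 strongest regions of each list by fold with their nearest gene. They also include the 10 genes with the highest fold among those marked in each list alone and up to 10 oxidative phosphorylation (OXPHOS) genes marked in one list alone. From every other list come up to 4 members marked in one list alone and up to 2 marked in both. Some genes that the rule takes are not reported here. Alternatives fixed in advance were stricter thresholds on −log10 q and fold, a 50% reciprocal overlap, equal numbers of strongest regions, stitching within 1 kb, windows of 3 kb, summits in place of regions and unmatched random lists. Counts without the longest gene-free stretch of each chromosome, or over the whole gene span, were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.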

Results

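H3K14ac was mapped in MKN45 gastric cancer cells with a control hairpin or with a hairpin against NIT2, an omega-amidase of glutamine metabolism. The study's title places NIT2 upstream of oxidative phosphorylation and of resistance to fluorouracil, so the comparison asks which genes carry the mark when NIT2 is knocked down. Each condition had 1 H3K14ac library, so no difference below has a replicate check. The 2 libraries were of unequal depth. The median pileup at a summit was 6 fragments in the control (quartiles 4 and 9) and 22 in the NIT2 knockdown (quartiles 16 and 31), and the background floors differed 8.93-fold.

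The control list held more but narrower regions, and 45.7% of them lay in the longest gene-free stretch of their chromosome. It had 39876 regions covering 19.6 Mb (median width 366 bp), against 28187 regions covering 22.1 Mb (median width 573 bp) in the knockdown list. The order of the counts turned at −log10 q of at least 5, with 14033 control and 17049 knockdown regions. A given q is harder to reach in the shallower control, so depth may give such a turn. The longest gene-free stretch of each chromosome, 24 stretches with 194.6 Mb or 6.30% of the genome, held 18213 control regions (95% interval of the share 45.2 to 46.2). The same stretches held 3 knockdown regions, 0.0106% of that list. On chromosome 18, the stretch from 15330264 to 20946905 alone held 2757 of the 3175 control regions and 0 of the 621 knockdown regions. Random shifts of the control list put 5.62% of its regions in such stretches on average and 15.8% at most. Outside them, the control list kept 21663 regions covering 7.98 Mb.

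**Figure D1:**
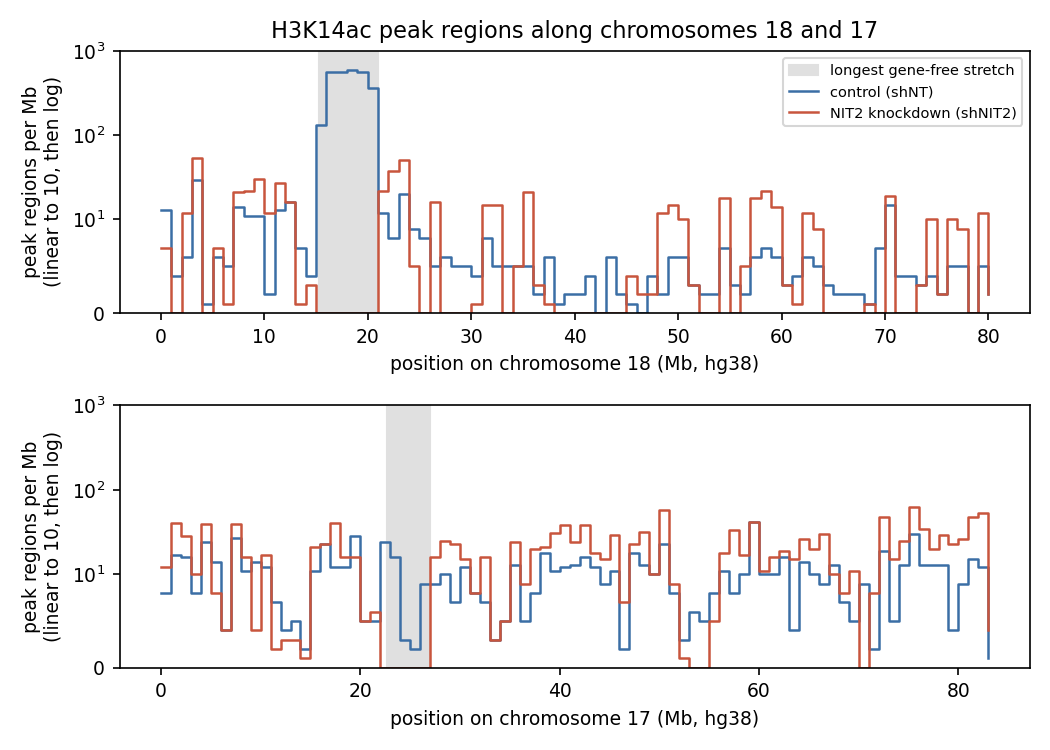
Peak regions per Mb along chromosomes 18 and 17 (position in Mb, hg38) in the control and the NIT2 knockdown list, on an axis that is linear to 10 and logarithmic above. In the shaded gene-free stretch of chromosome 18 the control list held 2757 regions and the knockdown list 0.

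The strongest regions of the lists differed in kind. By the authors' fold, the top control region lay on chromosome 10 from 41839414 to 41840106 (51.2-fold), in a gene-free stretch. So did those on chromosome 12 from 37248791 (44.4-fold) and on chromosome 20 from 26600179 (41.2-fold). The second control region, on chromosome 14 from 49586588 to 49586874 (45.4-fold), lay in the span of RPS29, a ribosomal protein gene, and overlapped RN7SL1, the RNA of the signal recognition particle. Of the 5 strongest control regions, 1 was shared, on chromosome 11 from 62043875 to 62044656 (40.5-fold), with the ferritin heavy chain gene FTH1 as its nearest protein-coding gene 76241 bp away. All 5 strongest knockdown regions were shared. They lay 2999 bp from ALDH3A1, an aldehyde dehydrogenase (chromosome 17, 19751297 to 19754603, 53.7-fold), over the cytoplasmic actin gene ACTG1 (53.2-fold), 927 bp from S100A2 (45.2-fold), in the histone H3K4 methyltransferase gene SETD1B (43.8-fold) and 3105 bp from ONECUT3 (43.7-fold).

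The lists shared few regions, yet far more than random placement gave. Of the control regions, 3613 or 9.06% (8.78 to 9.35) overlapped a knockdown region, against a random mean of 1.23% and a maximum of 1.76%. Of the knockdown regions, 3300 or 11.7% (11.3 to 12.1) overlapped a control region, against a random mean of 1.64% and a maximum of 2.31%. Outside the gene-free stretches the control share was 16.7% (16.2 to 17.2), with a random mean of 1.11%. Stronger knockdown regions were shared more often, from 2.64% at −log10 q under 2 to 60.7% (57.6 to 63.8) of the 1006 regions above 50. Control regions outside the stretches rose from 6.08% to 67.0% (57.3 to 75.7) of the 109 regions between 20 and 50. Above 50 there were 12, of which 41.7% (15.2 to 72.3) were shared. A 50% reciprocal overlap lowered the shares to 2.07% and 2.93%.

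**Figure D2:**
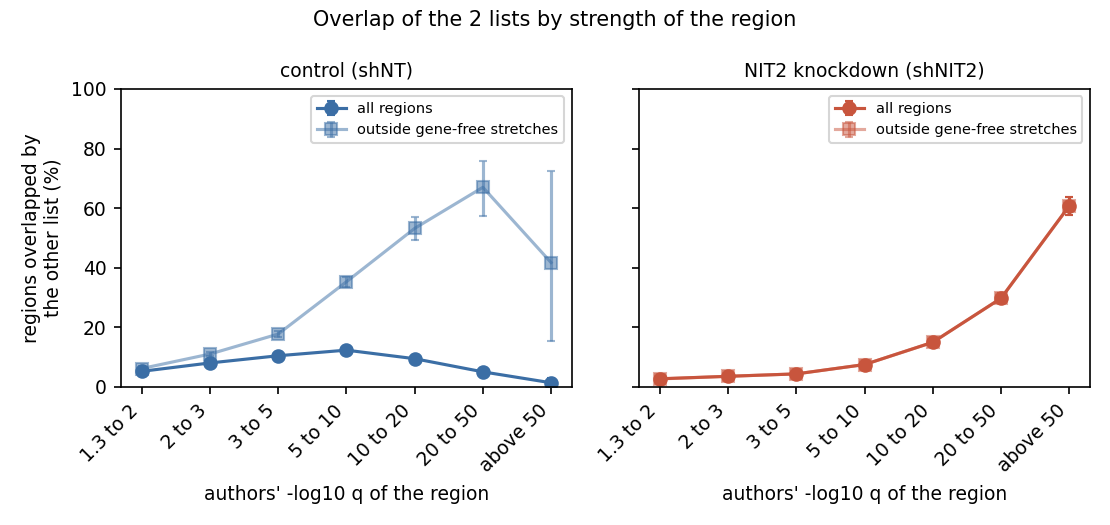
Percent of regions overlapped by the other list (vertical axis) by the authors' −log10 q of the region (horizontal axis), for the control and the NIT2 knockdown list. Bars are exact 95% intervals, and the share of knockdown regions rose from 2.64% to 60.7%, and the control share rose with strength up to −log10 q 50 only outside the gene-free stretches.

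Knockdown regions gathered at gene ends. Control regions did so weakly as a whole, and mainly where they were shared with the knockdown list. Midpoints fell within 1 kb of a gene end for 25.1% (24.6 to 25.6) of the knockdown regions and 2.69% (2.53 to 2.85) of the control regions. Outside the gene-free stretches the control share was 4.95% (4.67 to 5.25). That value joins unlike groups. Of the 3613 shared control regions 19.8% lay at gene ends, against 1.99% of the 18052 unshared ones outside the stretches. Knockdown regions showed no such split, with 20.03% of the shared and 25.8% of the unshared ones outside the stretches. Shared regions overlap knockdown regions by definition, so their places are not independent of that list. Counting every region that touched a gene end, the knockdown list stood 7.84-fold over its random placement. The control list stood 1.901-fold over it outside the stretches and 0.958-fold over it in all. Between protein-coding genes lay 75.5% of all control regions, 54.8% of those outside the stretches and 33.2% of the knockdown regions. Regions inside genes made up 40.2% of the control list outside the stretches and 41.7% of the knockdown list.

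**Figure D3:**
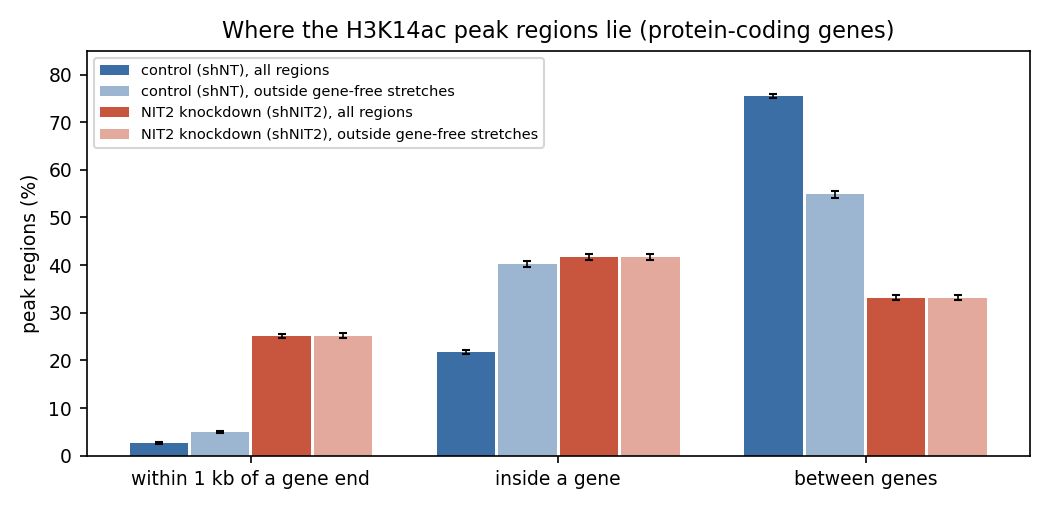
Percent of peak regions whose midpoint lay within 1 kb of either end of a protein-coding gene, inside a gene or between genes, for all regions and for those outside the gene-free stretches. Bars start at 0 and carry exact 95% intervals for counting error. At gene ends lay 25.1% of the knockdown and 2.69% of the control regions.

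Many more genes were marked in the knockdown list. Of 20037 protein-coding genes, 7373 (36.8%) had a region at a gene end in the knockdown list and 1285 (6.41%) in the control list. Both lists marked 1026 genes, where independent lists of these sizes would share 473. The knockdown list alone marked 6347 and the control list alone 259. Over the whole gene span, a count added after seeing the data, these numbers were 5492 and 1784. NIT2 itself (chromosome 3, 100334757 to 100361635) was marked in the knockdown list alone, by a region from 100334834 to 100335486 (6.23-fold). The nearest control region began 2777 bp inside the gene, on 3 fragments. Acetylation at the gene does not measure the knockdown, so this checks no label. RELA, an NF-kB subunit (5.79-fold), and BRD1, a scaffold of H3K14 acetyltransferases (6.90-fold), were marked in the knockdown list alone. The acetyltransferase gene KAT7 was marked in neither list, with the nearest knockdown region 133587 bp away.

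The folds of genes marked in one list alone rank them within that list and are not compared between lists, since the pseudocount lowers folds more in the shallower control. The strongest in the knockdown list were CDC42, a small GTPase (29.4-fold), DAZAP1, an RNA-binding protein (29.0-fold), SENP3, a SUMO protease (25.3-fold), and DENND3 (24.6-fold). CNOT3 of the CCR4-NOT deadenylase (24.1-fold), the circadian factor NPAS2 (23.9-fold), the integrin subunit ITGA2 (23.3-fold), the netrin NTN4 (22.96-fold), TSPAN3 (21.4-fold) and the methylcytosine dioxygenase TET3 (21.0-fold) followed. In the control list the highest value, 7.85-fold on 11 fragments, came from 1 region (chromosome 6, 44218779 to 44219028). It lay near both MYMX, a myoblast fusion factor, and SLC29A1, a nucleoside transporter. FBXL4, which acts in mitochondria, followed at 7.83-fold, then ZNF124 (7.49-fold), OOSP2 (7.35-fold), DYNLT2B and MADCAM1 (both 7.22-fold). SMG6 and SRR shared 1 region at 7.22-fold, and HEMK2 had 7.04-fold. The 259 genes of the control list alone had a median of 4 fragments and at most 11.

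The OXPHOS genes, which encode the respiratory chain and ATP synthase, were often marked in the knockdown list. Of 84 subunit genes, 44 were marked in the knockdown list alone, 9 in both lists, 0 in the control list alone and 31 in neither. Complex V had 14 of 18 genes marked in the knockdown list alone, complex III 7 of 9, complex I 15 of 37, complex IV 6 of 16 and complex II 2 of 4. These counts include cytochrome c (CYCS), listed with complex IV, and the ATP synthase inhibitor ATP5IF1, listed with complex V, which are not subunits. Both were marked in the knockdown list alone and were named after their values were seen. Among the subunit genes marked in the knockdown list alone, the highest folds belonged to UQCRFS1, the Rieske protein of complex III (11.6-fold), NDUFB1 of complex I (10.2-fold), and ATP5F1E (9.24-fold) and ATP5F1B (8.85-fold) of ATP synthase. CYC1 (7.60-fold), COX4I1 (7.47-fold), NDUFA11 (7.28-fold) and ATP5F1D (7.08-fold) came next. Of 49 assembly factors, 24 were marked in the knockdown list alone, led by COX19 (11.4-fold) and NDUFAF3 (7.95-fold), and 4 in both. COX14, named after its values were seen, was marked in the control list alone on 4 fragments. The 44 subunit genes compare with a mean of 25.5 in unmatched random lists (percentile 100). By complex, the unmatched percentile passed the upper limit for complex III (99.7) and complex V (99.98), and did not for complexes I (88.97), II (76.6) and IV (71.6). It was 98.995 for the assembly factors. Among random lists matched on peak strength the mean was 42.1 (range of the central 95%, 36 to 47) and the percentile 72.3, which ranged over the alternatives from 15.0 at −log10 q of at least 5 to 82.9 outside the stretches. The matched percentile was 45.9 for the assembly factors and, for complexes I to V in turn, 39.0, 56.6, 46.1, 64.4 and 78.6. Pooled, the subunit genes were thus marked in the knockdown list alone more often than genes at large, with complexes III and V past the limit on their own. Matched lists hold as many marked genes by construction, and the mean rank they are matched on partly fixes the division too. Their percentile therefore says little about how marked OXPHOS genes divide between the lists.

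The marked genes of other metabolic lists were also mostly marked in the knockdown list alone. Of 76 mitochondrial ribosomal protein genes, 44 were marked in the knockdown list alone, among them MRPL23 (13.8-fold) and MRPL2 (11.1-fold), with 2 in both. The mitochondrial biogenesis regulators had 9 of 20, including GABPB1 (9.26-fold) and ESRRA (8.48-fold). The TCA cycle had 11 of 19, with IDH2 (7.09-fold) and SUCLG2 (6.77-fold), and MDH2 in both. Fatty acid oxidation had 10 of 18, with ETFB (11.6-fold) and CPT2 (8.19-fold). Glycolysis, which is not mitochondrial, had 11 of 22, with PFKL (16.3-fold) and GAPDH (13.1-fold), while ENO1 and PKM were marked in both. In this order, the unmatched percentiles were 100, 90.2, 99.0, 98.3 and 96.7, so the biogenesis regulators and glycolysis stayed within the limits. The matched percentiles were 71.4, 77.5, 75.4, 76.2 and 91.5. For glycolysis the matched value ranged over the alternatives from 42.9 at −log10 q of at least 5 to 98.0 with windows of 3 kb.

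Genes that handle fluoropyrimidines, the class of fluorouracil, were marked in the knockdown list alone in 13 of 24 cases. They included thymidine phosphorylase TYMP (12.9-fold), cytidine deaminase CDA (10.3-fold), FPGS (8.04-fold) and RRM2 (7.98-fold). Thymidylate synthase TYMS, the drug's target, was marked in both lists, as was UPP1. SLC29A1 was marked in the control list alone. The matched percentile was 25.6, and ranged from 1.04 at −log10 q of at least 5 to 54.9 with windows of 3 kb. The unmatched one was 97.3. Of 22 genes of NIT2 and glutamine metabolism, 9 were marked in the knockdown list alone, including the transporters SLC38A2 (9.11-fold) and SLC38A1 (8.45-fold). GPT2 and KYAT3 were among 3 marked in both. The matched percentile was 6.97, and ranged from 1.80 with windows of 3 kb to 57.3 with equal numbers of strongest regions. The unmatched one was 71.2.

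The list of H3K14 acetylation writers and readers, which also holds the deacetylase HDAC1, had 14 of 27 genes marked in the knockdown list alone. These included TADA3 (8.95-fold), BRPF3 (8.31-fold) and EP300 (8.05-fold). A further 6 were marked in both, including ZMYND8 and HDAC1 (matched percentile 5.24, as for the lists that follow). The NF-kB pathway had 11 of 29 in the knockdown list alone, including NFKBIA (7.401-fold) and BIRC2 (6.90-fold), with IKBKG in both (74.9). Among p53 targets and apoptosis genes, 12 of 24 were marked in the knockdown list alone, with CDKN1A at 13.1-fold, and 6 in both, with MDM2 the strongest (64.1). Cell cycle genes had 16 of 32, with E2F1 at 8.38-fold, and 7 in both, including MCM7 (20.6). DNA repair genes had 12 of 25, with XPC at 11.98-fold (78.4), and stress response genes 11 of 22, with ATF4 at 13.5-fold (38.2). Gastric cancer oncogenes and receptors had 14 of 20, with VEGFA at 11.5-fold, and 3 in both, including MET and EGFR (76.6, from 23.4 at −log10 q of at least 5 to 98.5 with windows of 3 kb). Cytosolic ribosomal protein genes, active in all growing cells, had 56 of 73, with RPL10A at 16.6-fold, and 16 in both, with RPS19 the strongest (54.5). Genes of drug efflux and detoxification had 6 of 18, with the exporter ABCC1 at 9.53-fold, and 7 in both, including NFE2L2 and KEAP1 (22.1). Unmatched, the cell cycle (98.5), gastric cancer (99.97) and cytosolic ribosomal lists (100) passed the upper limit. The other 6 lists lay between 60.2 and 97.1. Besides COX14 and SLC29A1, the genes of these lists marked in the control list alone were MRPS27, OGDHL, KAT8 and RPL6, on 3 to 5 fragments each, and they were named after their values were seen.

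Epithelial genes were marked in the knockdown list alone more often than genes at large, and neuron, muscle and liver markers less often. Of 41 epithelial and gastrointestinal genes, 21 were marked in the knockdown list alone, led by MUC1 (17.2-fold) and ESRP2 (16.6-fold). A further 10 were marked in both, including CEACAM6 (matched percentile 82.2). Mesenchymal genes had 3 of 20 marked, ACTA2 (9.54-fold), VIM (4.30-fold) and ZEB1 (3.37-fold), all in the knockdown list alone (59.8). Immune cell markers had 4 of 17, CD68, CD3D, LYZ and CD3E, at 5.79-fold or less (61.2). Neuron markers had 1 of 16, NEFL (52.97), and muscle and liver markers 1 of 21, TTR (53.7). The unmatched percentiles were 99.6 for the epithelial genes, 2.15 for the neuron markers and 0.525 for the muscle and liver markers, past the limits. They were 7.96 for the mesenchymal genes and 28.8 for the immune markers, within them. The lists were not tested against each other. The control list marked none of the genes of these last 4 lists.

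**Figure D4:**
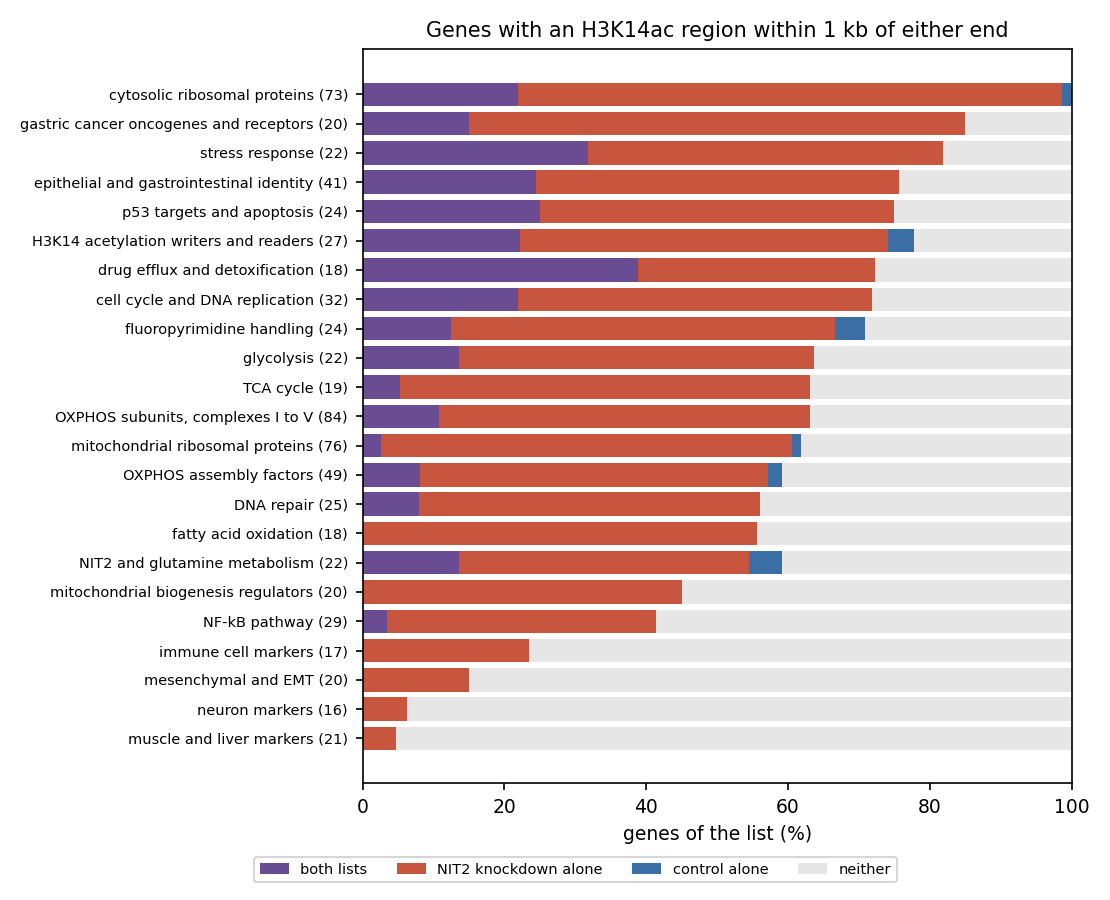
Percent of the genes of each list (number of genes in parentheses) with an H3K14ac region within 1 kb of either gene end in both lists, in the NIT2 knockdown list alone, in the control list alone or in neither. Of the 84 OXPHOS subunit genes, 44 were marked in the knockdown list alone, and of the 73 cytosolic ribosomal protein genes 56.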

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

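The overlap and counts outside the gene-free stretches, over the gene span and over every stretch of at least 1 Mb were chosen after seeing the data. Among the main counts and shares, 37 values under alternatives stayed and 40 moved. A count stayed when within 1.5 times, a share when within its interval, and a percentile when on the same side of both limits, however far it shifted between them. This was scored for each list by itself, not for the order of the 2 lists, which did turn in places. For the other gene lists, 222 stayed and 21 moved. At −log10 q of at least 5, the control list held 14033 regions (9.72 Mb) and the knockdown list 17049. At 10 they held 5524 (4.58 Mb) and 9134 (11.7 Mb), and at a fold of at least 5 they held 18719 (11.9 Mb) and 9687 (11.8 Mb). Outside the stretches the control list held 21663 (7.98 Mb). The control list thus had more regions as deposited and at a fold of at least 5, and fewer at both stricter q thresholds and outside the stretches. The same q or fold threshold is not equally strict in libraries of unequal depth, so these orders do not compare acetylation. The control and knockdown overlap shares were 2.07% and 2.93% with a 50% reciprocal overlap, 9.84% and 7.57% at −log10 q of at least 5, and 8.34% and 14.7% at a fold of at least 5. They were 10.3% and 9.54% for equal numbers of strongest regions, and 11.1% and 14.6% with regions stitched within 1 kb. Regions at −log10 q of at least 10 against the whole other list gave 7.53% and 25.04%, and the control share outside the stretches was 16.7%. The control share was the higher one at −log10 q of at least 5, with equal numbers and outside the stretches, and the knockdown share as deposited and in the other settings. Gene ends took 5.69% of control and 34.4% of knockdown regions with windows of 3 kb, and 1.72% and 28.7% at −log10 q of at least 5. They took 25.99% of knockdown regions by summit and 4.95% of control regions outside the stretches. Genes marked in both lists numbered 1771 with windows of 3 kb, 265 at −log10 q of at least 5 and 3926 over the gene span. Those marked in the control list alone numbered 648, 39 and 1784, and 131 with equal numbers of regions. Over the gene span the knockdown list alone marked 5492 genes, so the lists lay much closer there than at gene ends. The OXPHOS subunit percentile was 100 in unmatched lists. Stricter thresholds leave fewer regions and wider windows more by construction; the cause of the other shifts was not tested. Windows at the 5′ end alone or at every start site, and exon and intron classes, were not run, since the gene table used here gives no strand or exons. Depth limits the control list: its weakest regions rest on 3 fragments, so a gene unmarked there is not shown to be unacetylated. Depth may not be the only limit. By their summits, 2833 genes marked in the knockdown list were expected to be callable at the control's depth. Both lists marked 1026. The 2833 may be too high by an unknown amount. It rests on summits selected as peaks and asks only whether a summit passes, not whether a region is wide enough to be called. It also counts control fragments in regions of the gene-free stretches, at most 22.7% of them. No paired analysis was possible because each condition had 1 library.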

Other observations

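All tests below except that of the OXPHOS genes were chosen or restated after the result was seen; the explanation tested as an even loss of enrichment was narrowed once its value was known. Genes of drug efflux and detoxification were the list most often marked in both conditions for the strength of their knockdown regions. Of 13 marked in the knockdown list, 7 were also marked in the control list (ABCC3, GSTP1, NQO1, GCLM, TXNRD1, NFE2L2 and KEAP1), against a matched random mean of 3.33 (percentile 98.8). The first 5 of these were named after their values were seen. The list of H3K14 acetylation writers and readers stood at percentile 97.6, with 6 in both, the deacetylase HDAC1 among them, against a mean of 2.72. With 27 lists examined, percentiles this far out can arise by chance. Background along the genome ran alike behind both lists, whether the inputs or the H3K14ac libraries set it. The 1 Mb window from 116000001 on chromosome 7 holds MET. There the background stood at 12.9 times the median window in the control and 13.2 times in the knockdown. Across 528 windows Spearman's rho was 0.797, part of which any human libraries may share through mappability. MKN45 is known to carry an amplified MET gene.

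The first pattern is the scarcity of control regions at gene ends and the small overlap. Lower depth as the whole cause, scaled by the ratio of floors, predicted that 31.0% of knockdown regions would pass at the control background (97.7% above −log10 q of 50). Of the knockdown regions, 11.7% (60.7%) were shared, and 339 of 753 control regions at 10 or more outside the stretches were missing from the deeper list. The prediction takes the summit alone and not the width of the region. The scaling also counts control fragments in regions of the stretches, at most 22.7% of them. The predicted shares may therefore be too high by an unknown amount. The fitted loss and the ratios by place given below rest on the same calculation, so widths that differ by place could shift them. That 1 library came from a line without the amplified MET region is argued against by the background of that window, at least 12.9 times the median in both. If the inputs served as the control, that background may be theirs and then speaks only to the origin of the inputs. An MKN45 sample from outside the study stays open. An even loss of enrichment, fitted to 50% of the excess over background, gives the overlap in all (11.8%) because it was fitted to it. It predicts 12.8% at gene ends and 11.4% elsewhere, against 9.33% (8.66 to 10.0) and 12.5% (12.1 to 13.0). Above 50 it predicts 70.6% and 73.6%, against 56.7% (50.02 to 63.1) and 62.0% (58.4 to 65.4). As the whole cause it thus misses by place and by strength, as far as the summit alone decides what is called. Sharing fell short of the depth expectation everywhere, to 0.417 (0.402 to 0.432) of it elsewhere and 0.275 (0.255 to 0.295) at gene ends, a quotient of 0.659, while above 50 the ratios of 0.634 and 0.583 had overlapping intervals; a broad loss with an excess at gene ends stays open, which may be lower acetylation in control cells, as the hairpin contrast allows, or weaker precipitation with a GC or fragmentation bias of 1 library, none of which was tested.

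The second pattern is the crowd of control regions in gene-free stretches. If the background was set alike in both lists, lower depth would give fewer regions everywhere. Yet the deeper knockdown list held 3 regions in the stretches, against 18213 in the control list. How the background was set is not given, so an effect of depth through the background stays open. Random placement put at most 15.8% of control regions there against 45.7%. Differently kept or controlled repeat reads and acetylated satellite chromatin in control cells cannot be told apart: 88.9% of these regions had a background above the floor, so reads of the input or of the library itself raised it, and reads of the inputs would be needed to decide.

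The third pattern is the OXPHOS genes marked in the knockdown alone. If they had gained H3K14ac beyond gene ends of like strength, fewer than in matched lists would also be marked in the control. Of 53 marked in the knockdown, 9 were marked in both, against a matched mean of 6.18 and a percentile of 88.7, which argues against a gain beyond that of other genes of like strength. A gain shared by many gene ends, OXPHOS among them, stays open and untested, since 1 library per condition cannot separate it from a difference between the libraries.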
